A study of Mus musculus with 18 samples.

How the data were processed

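Small RNA was measured in 18 libraries of mouse intima in 4 groups, from LDL receptor knockout males fed LCD or HCD for 9 weeks and sequenced with a traditional protocol or with PANDORA-seq. Per the labels' protocols, total RNA was extracted with Trizol, RNA of 15 to 50 nt was taken from a urea polyacrylamide gel, and libraries were made with the NEBNext small RNA kit, with T4 polynucleotide kinase and AlkB treatment first for PANDORA-seq. The deposited files list each distinct clean read sequence with its length in nt and its raw read count, per the file headers. No annotation, normalization or adapter trimming tool is recorded, and the mm10 genome build is named in the submitters' processing notes without a stated use. The counts were checked to be whole numbers of at least 1, and the lengths equalled the sequences' lengths (15 to 45 nt).

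Sequences were named from exact matches, since the files hold no annotation. miRNA genes, snoRNAs, snRNAs, Y RNAs, mitochondrial RNAs and longer transcripts came from GENCODE mouse release 21, and gene names from RefSeq on GRCm38 patch 6, whose coordinates are printed for Mir21a. That annotation holds no full-length nuclear rRNA and no nuclear tRNA sequence. Both were therefore rebuilt from the pooled reads themselves: 9 rRNA contigs of 140 to 2425 nt that hold known rRNA stretches, and 289 tRNA contigs of 25 to 84 nt, kept by cloverleaf pairing, anticodon and known 5' ends of 12 nt. These contigs were refined several times while looking at how many of these reads they matched, so the rRNA and tRNA shares depend on this reference, and names of tRNA fragments rest on it. The contigs can run past the ends of the mature rRNA, and reads of such flanks count as that rRNA. A read matching several features went to a joined feature named after all of them, or, beyond 4 names, after the first with the word group and letters. Of 3698 features with a read, 1174 carry several names. A read matching several classes went to miRNA first, then rRNA, tRNA, Y RNA, snoRNA, snRNA and others, and sequences under 18 nt were not matched to longer transcripts. tRNA pieces were called 5' end when they started within 2 nt of the 5' end, 3' end when they ended within the last 5 nt, CCA end when they carried the added CCA, and internal otherwise. A genome sequence and a piRNA reference were not used here, so the planned shares of genome-matched reads were not computed and piRNA was left out.

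Counts per feature were compared with edgeR 4.0.16 in R 4.3.3: glmQLFit with robust estimation, glmQLFTest (two-sided), TMM scaling within the fit, filterByExpr by group, library size as the sum over features and Benjamini-Hochberg adjusted p under 0.05 over the features of that fit. Diet effects were fitted in each method alone (HCD over LCD). Sequences seen in at least 9 reads in total entered a fit of their own, with library size as the sum over tested sequences. The method effect used all 18 libraries with diet as covariate and total clean reads as library size without TMM, and the interaction used diet, method and their product with TMM. The SE of a log2 fold change is its size over the square root of F. CPM values are read counts scaled to a common size, 1000000 reads of that fit's scaled library size, as computed here. Class shares (9 classes) and mean lengths were compared with two-sided exact permutation tests of the difference of means over all divisions of the libraries. They were computed directly in Python and adjusted over the 9 classes of a comparison or the 16 length tests. Spearman's rho was computed with SciPy 1.17.1. Lists of miRNAs (15, fixed before the data were examined), the tRNA isotypes and the rRNA species were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with the estimated correlation beside it, where at least 3 members were measured.

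Features are named by a rule set before the data were examined. Among features past the threshold with a mean of at least 10 CPM, these are the 5 miRNAs, 4 tRNA fragments and 2 others with the largest rise and the largest fall by diet (5, 5 and 3 by method), and the 2 tRNA and 2 rRNA sequences each way. Where a class had none, the 3 features of lowest p are given as values, and for the interaction the 5 of lowest p. rRNA species and Y RNAs are always given. List members are given as the 2 of highest mean CPM. The rule allowed 2 to 4, and 2 was settled on after the values had been seen.

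The tests were run on simulated counts with 200 changed features drawn from the real means and spread. For the PANDORA-seq diet fit on 688 features, 60% of 2-fold and 99% of 4-fold changes were recovered, and for the traditional diet fit on 945 features 50% and 90%. For the method fit on 1083 features these were 64% and 96%, and for the interaction on 1089 features 15% and 81%. For single sequences, PANDORA-seq recovered 1.5% of 2-fold, 26.9% of 4-fold and 98.5% of 16-fold changes (20195 sequences), and traditional libraries 0%, 1.5% and 75.8% (19586 sequences). False calls were 11 of 170 in the PANDORA-seq and 6 of 146 in the traditional feature fit, 5 of 165 by method and 2 of 98 for the interaction. For sequences they were 10 of 94 with PANDORA-seq and 3 of 54 in traditional libraries. Features were drawn independently with rises and falls balanced, so shifts shared by many features were not simulated. Each feature had 1 mean over all libraries of its fit, apart from the simulated change. The real differences between the methods were thus left out of the method and interaction simulations. Features scarce in 1 method were simulated as more abundant there, so recovery for these 2 fits may not hold for the real data. The first simulation of sequences used 2-fold and 4-fold changes only and recovered none, and the 16-fold size was added after that.

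Same-numbered libraries were checked for shared deviations over 155 features. Between the methods on LCD every pair correlated above 0.1 (0.275 to 0.737), so by the rule used these numbers pair the samples there, a hint from the data, since the labels do not say so. Of these 4 pairs 3 correlated best with their own number, while replicate 3 had 0.275 with its own and 0.302 with another. The other comparisons had pairs at or below 0.1, and the numbers were not treated as pairs there. Between the methods on HCD this was replicate 4 (0.073). The 5 HCD pairs reached 0.577, and 4 of them correlated best with their own number, so pairing stays possible there. Pairs between the diets reached down to −0.302. The main method and interaction fits took all 18 libraries as independent, also on LCD, and a block on the replicate number is an alternative.

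Alternatives were DESeq2 1.42.0 with its size factors, other scalings, other filters on low counts, unique names only, 18 to 45 nt reads, other denominators, all libraries in 1 fit, a replicate block, and each library left out. Alternatives added after the data were seen allow 1 mismatch, insertion or deletion, put rRNA and tRNA before miRNA, keep reads of at most 35 nt, or apply to the lists and the length profile. Other splits of the samples, 100 per comparison, were refitted in the same way. Other tools were Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3.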

Results

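Small RNA of 15 to 50 nt was sequenced from the intima, the inner layer of the artery wall, of male mice that lack the LDL receptor. The mice were 3 weeks old at the start and ate a low cholesterol diet (LCD) or a high cholesterol diet (HCD) for 9 weeks. Each diet was sequenced with a traditional small RNA library and with PANDORA-seq, in which T4 polynucleotide kinase repairs RNA ends and the demethylase AlkB removes base methylations before the library is made. There were 4 LCD traditional, 4 LCD PANDORA-seq, 5 HCD traditional and 5 HCD PANDORA-seq libraries. Each held between 16912688 and 60972488 clean reads of 15 to 45 nt, spread over 671731 to 5862844 distinct sequences per library. The range was 39067490 to 60578506 reads in LCD traditional, 41985708 to 46932337 in LCD PANDORA-seq, 16912688 to 53508380 in HCD traditional and 33057109 to 60972488 in HCD PANDORA-seq libraries. The labels do not say whether each library came from a separate animal, so the p-values measure the spread between these samples.

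The first comparison asked which RNA classes each method captured. miRNA made up 43.9% ± 5.54 (SD, n = 4) of traditional reads on LCD and 0.436% ± 0.109 (SD, n = 4) of PANDORA-seq reads. Ribosomal RNA fragments went the other way, from 7.78% ± 2.65 to 70.2% ± 2.68 (SD, n = 4 each). On HCD the miRNA share was 51.0% ± 11.7 in traditional and 0.687% ± 0.124 in PANDORA-seq libraries, and the rRNA share 5.96% ± 2.56 and 70.9% ± 2.41 (SD, n = 5 each). Fragments of nuclear tRNA were 18.7% ± 2.54 of traditional and 4.80% ± 1.44 of PANDORA-seq reads on LCD (SD, n = 4 each), and 14.3% ± 6.59 and 4.12% ± 0.748 on HCD (SD, n = 5 each). Reads with no match to the reference took 27.1% ± 4.53 of traditional and 16.9% ± 0.636 of PANDORA-seq reads on LCD (SD, n = 4 each). The tRNA and unmatched shares depend on exact matching. With 1 mismatch, insertion or deletion allowed, tRNA took 28.9% instead of 19.7% in LCD_traditional replicate 1. In LCD_PANDORA replicate 1 it took 4.23% instead of 3.17%. Unmatched reads then took 9.86% instead of 24.0% and 8.09% instead of 16.5% in these libraries. In two-sided exact permutation tests, 8 of 9 classes differed between the methods on LCD (adjusted p = 0.0321 for each), and mitochondrial rRNA did not pass (adjusted p = 0.4). On HCD 7 of 9 passed, and mitochondrial tRNA (adjusted p = 0.125) and Y RNA (adjusted p = 0.294) did not. On LCD the call of mitochondrial tRNA ended without any 1 of the 4 PANDORA-seq libraries (adjusted exact p = 0.0643), that of snoRNA and snRNA without any 1 of the 4 traditional libraries (0.0964) and that of Y RNA without LCD_traditional replicate 2 (0.0735). On HCD mitochondrial rRNA lost its call without any 1 of the 5 traditional libraries (adjusted exact p up to 0.102). Same-numbered LCD libraries of the methods deviated together, and sign flips over these 4 pairs called 0 of 9 classes, since 4 pairs cannot give a p under 0.125.

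**Figure D1:**
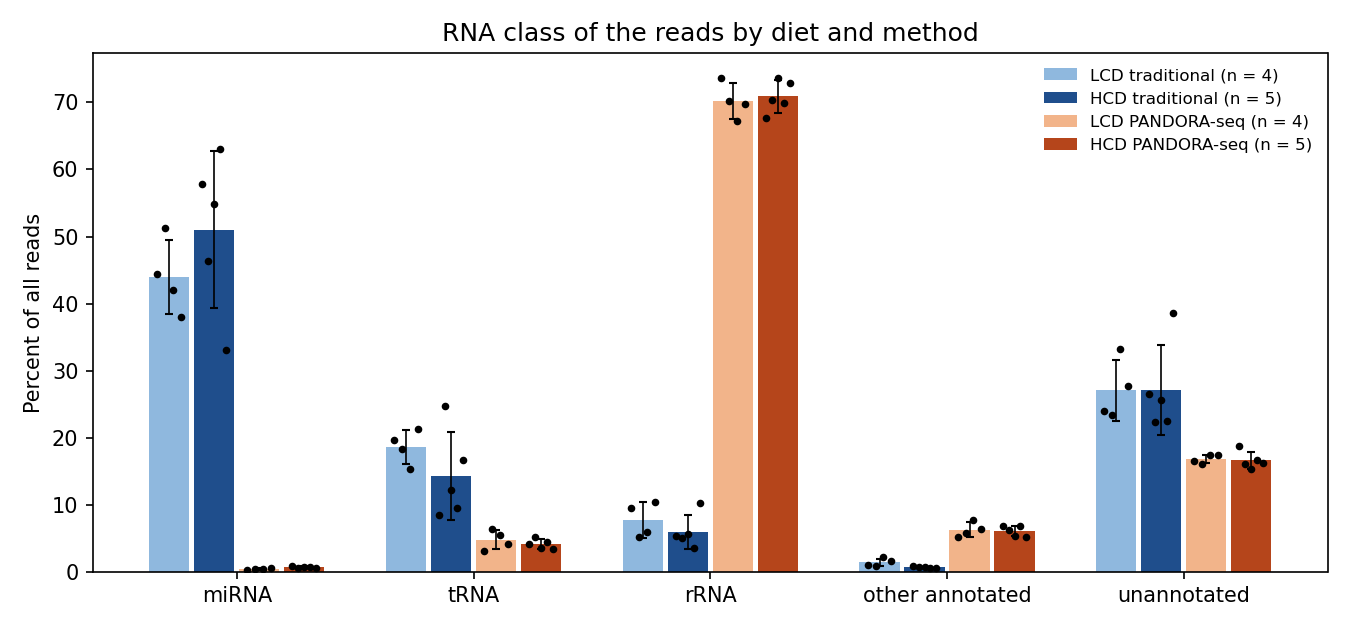
Percent of all reads in 5 RNA classes (y axis) for each diet and method; bars are means, error bars 1 SD and points single libraries. rRNA fragments take 70.2% and 70.9% of PANDORA-seq reads and miRNA 43.9% and 51.0% of traditional reads.

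PANDORA-seq reads were longer than traditional reads overall and in miRNA, tRNA and rRNA. The mean length on LCD was 36.2 nt ± 0.428 against 24.7 nt ± 0.395 (SD, n = 4 each), and on HCD 34.6 nt ± 0.492 against 23.9 nt ± 1.06 (SD, n = 5 each). rRNA reads averaged 36.9 nt ± 0.627 in PANDORA-seq and 30.1 nt ± 1.79 in traditional libraries on LCD (SD, n = 4 each), and tRNA reads 32.7 nt ± 0.470 and 30 nt ± 0.178. Some reads classed as miRNA also match rRNA or tRNA. With rRNA and tRNA put first, the miRNA share went from 0.324% to 0.269% in LCD_PANDORA replicate 1. In LCD_traditional replicate 1 it went from 44.5% to 44.4%. Lengths were not recomputed in that setting, so how far such reads lengthen the miRNA class was not tested. Within PANDORA-seq, HCD reads were shorter than LCD reads by 1.58 nt over all classes and by 1.55 nt in rRNA, a difference of −0.586 nt being measured in tRNA (exact permutation test, two-sided, adjusted p = 0.0317 each). All 5 HCD libraries lay below all 4 LCD libraries in overall and in rRNA length. The tRNA difference had an adjusted exact permutation p of 0.0762 without HCD_PANDORA replicate 1, 2 or 3 and 0.0703 without replicate 5. In traditional libraries miRNA reads were 0.0557 nt longer on HCD (adjusted p = 0.0254, exact permutation test), and the other 3 lengths by diet did not pass. Of 16 length tests 12 passed, and a block on the replicate number left 0 because 4 or 5 pairs cannot give an adjusted p under the threshold.

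**Figure D2:**
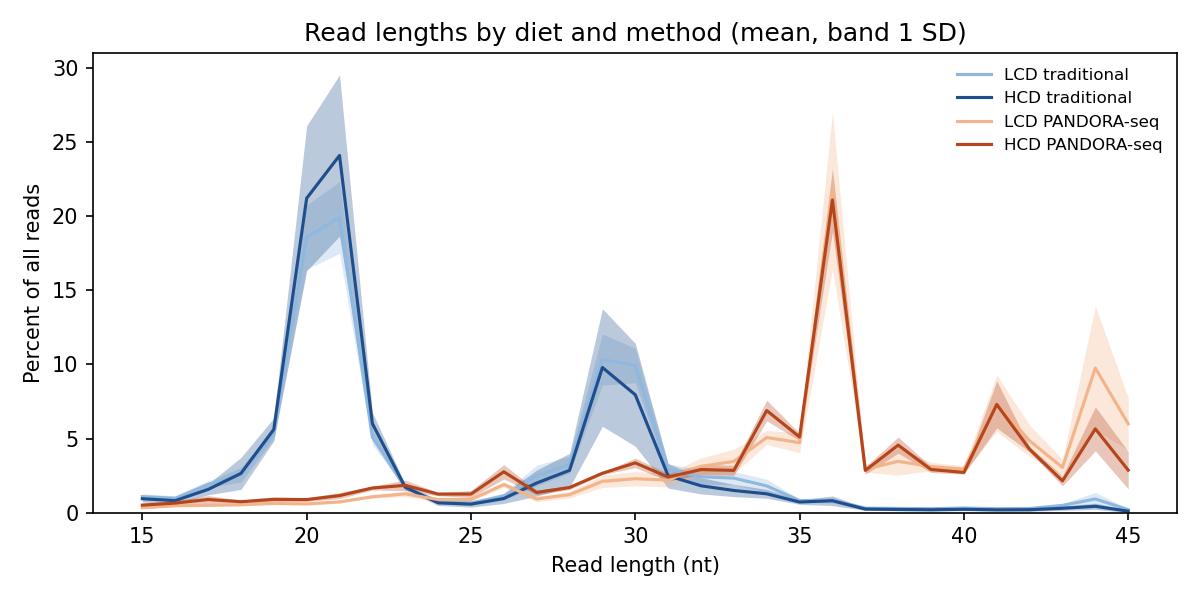
Read length in nt (x axis) against the percent of all reads (y axis), as the mean of each diet and method with a band of 1 SD. Traditional reads average 24.7 nt on LCD and 23.9 nt on HCD, and PANDORA-seq reads 36.2 nt and 34.6 nt.

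By diet, no class passed the test in either method. Y RNA, the small RNAs that bind the Ro60 protein, took 0.0470% ± 0.0103 (SD, n = 4) of LCD and 0.0243% ± 0.00656 (SD, n = 5) of HCD PANDORA-seq reads (exact permutation p = 0.00794, the smallest that 4 against 5 libraries allow; adjusted p = 0.0714). miRNA took 0.436% ± 0.109 on LCD (SD, n = 4) and 0.687% ± 0.124 on HCD (SD, n = 5) with PANDORA-seq (adjusted exact permutation p = 0.143). In traditional libraries the other annotated reads, most of them from longer transcripts, were 1.42% ± 0.577 on LCD (SD, n = 4) and 0.677% ± 0.121 on HCD (SD, n = 5; exact permutation p = 0.00794, adjusted p = 0.0714). rRNA differed between diets by 0.682 percentage points with PANDORA-seq (adjusted exact p = 0.817) and by −1.82 points in traditional libraries (adjusted exact p = 0.388).

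The diet effect on single small RNAs was tested first in PANDORA-seq libraries, with HCD over LCD as the direction (n = 5 and 4; log2 fold changes ± SE). miR-21a-5p, which is abundant in smooth muscle cells and macrophages, rose by 2.21 ± 0.25 on the log2 scale, from 18.6 ± 1.85 to 86.4 ± 18.6 CPM (mean ± SD; edgeR quasi-likelihood test, adjusted p = 0.000159). Its gene Mir21a lies on GRCm38 chromosome 11 at 86584067 to 86584158. The smooth muscle miRNA miR-145a-5p rose by 1.84 ± 0.38 (adjusted p = 0.0104, edgeR), and miR-140-3p, best known from cartilage, by 1.60 ± 0.29 (adjusted p = 0.0104, edgeR). miR-148a-3p, which represses the LDL receptor mRNA in liver, rose by 1.15 ± 0.29 (adjusted p = 0.0245, edgeR), from 103 ± 33.4 to 229 ± 58.8 CPM (mean ± SD). All 5 HCD libraries exceeded all 4 LCD libraries for these 4 miRNAs. miR-125a-5p fell by 1.07 ± 0.24 (adjusted p = 0.0167, edgeR), below every LCD library in 5 of 5. Among features shared by predicted miRNA genes, the Gm22369-3p group l rose by 1.07 ± 0.30 and the Gm22369-3p group aj fell by 1.27 ± 0.29 (adjusted p = 0.0338 and 0.0167, edgeR). The reads of the Gm47285 hairpin/Gm47301 hairpin feature fell by 1.20 ± 0.30 (adjusted p = 0.0245, edgeR), and 100% of them also match rRNA.

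Fragments of tRNA moved in both directions on HCD with PANDORA-seq. The 3' end of tRNA-Arg-TCT rose by 1.74 ± 0.50 (adjusted p = 0.0376, edgeR), the 3' end of mt-tRNA-v by 1.21 ± 0.33 (adjusted p = 0.0320) and internal pieces of tRNA-Trp-CCA by 0.95 ± 0.23 (adjusted p = 0.0215). The 5' end of tRNA-Pro-AGG fell by 1.85 ± 0.53 (adjusted p = 0.0444, edgeR), internal pieces of tRNA-Ser-GCT by 1.54 ± 0.36 (adjusted p = 0.0177), those of tRNA-Leu-AAG by 1.47 ± 0.38 (adjusted p = 0.0250) and the 5' end of mt-tRNA-q by 1.30 ± 0.28 (adjusted p = 0.0120). The Y RNA Rny3 fell by 1.82 ± 0.36, from 506 ± 266 to 143 ± 37.7 CPM (mean ± SD; adjusted p = 0.0104, edgeR), and the snoRNA Snord22 by 1.24 ± 0.26 (adjusted p = 0.0104, edgeR). The other Y RNA, Rny1, had −0.45 ± 0.26 (adjusted p = 0.289, edgeR). None of the rRNA species passed: 28S rRNA had −0.39 ± 0.22, 18S rRNA 0.19 ± 0.31, 5.8S rRNA −0.35 ± 0.23, 5S rRNA −0.91 ± 0.36, mt-12S rRNA 0.31 ± 0.35 and mt-16S rRNA 0.13 ± 0.32 (adjusted p from 0.122 to 0.819, edgeR). Without LCD_PANDORA replicate 2 5S rRNA had −0.39, without LCD_PANDORA replicate 3 −1.17, which passed, and without LCD_PANDORA replicate 1 28S rRNA had −0.15. In all, 77 of 688 features passed, 35 higher and 42 lower on HCD, among them 49 of 354 miRNA features and 14 of 115 nuclear tRNA features. The median of all features was 0.04, and 0.29 with total reads as library size, so directions are relative to it. The count was 17 without LCD_PANDORA replicate 1, 22 without LCD_PANDORA replicate 2, 34, 42 and 25 without HCD_PANDORA replicate 1, 3 or 4, and 49 with total reads as library size, under which 75.5% of calls were higher against 45.5%. LCD_PANDORA replicates 1 and 2 also had the lowest TMM factors, 0.643 and 0.815, against 0.958 to 1.243 in the other PANDORA-seq libraries. The calls of miR-21a-5p, miR-145a-5p and miR-140-3p held without each of the 9 libraries (1.42 to 2.29, highest adjusted p = 0.0498, edgeR). Those of the other features named here each ended without 1 to 8 of the 9 libraries. The mt-tRNA-v 3' end lost its call without 8, the tRNA-Pro-AGG 5' end and the Gm22369-3p group l without 6, and miR-148a-3p without 4. Rny3 had −1.50 and Snord22 −1.05 without LCD_PANDORA replicate 1 (adjusted p = 0.0542 and 0.0576, edgeR). The tRNA-Pro-AGG value was −0.81 without LCD_PANDORA replicate 2 (adjusted p = 0.206, edgeR), the mt-tRNA-v value 0.19 without reads under 18 nt (adjusted p = 0.739) and the tRNA-Ser-GCT value −0.44 without reads over 35 nt (adjusted p = 0.362). Without these longer reads the tRNA-Arg-TCT value was 0.90 (adjusted p = 0.114) and the mt-tRNA-q 5' end −0.66 (adjusted p = 0.139, edgeR).

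**Figure D3:**
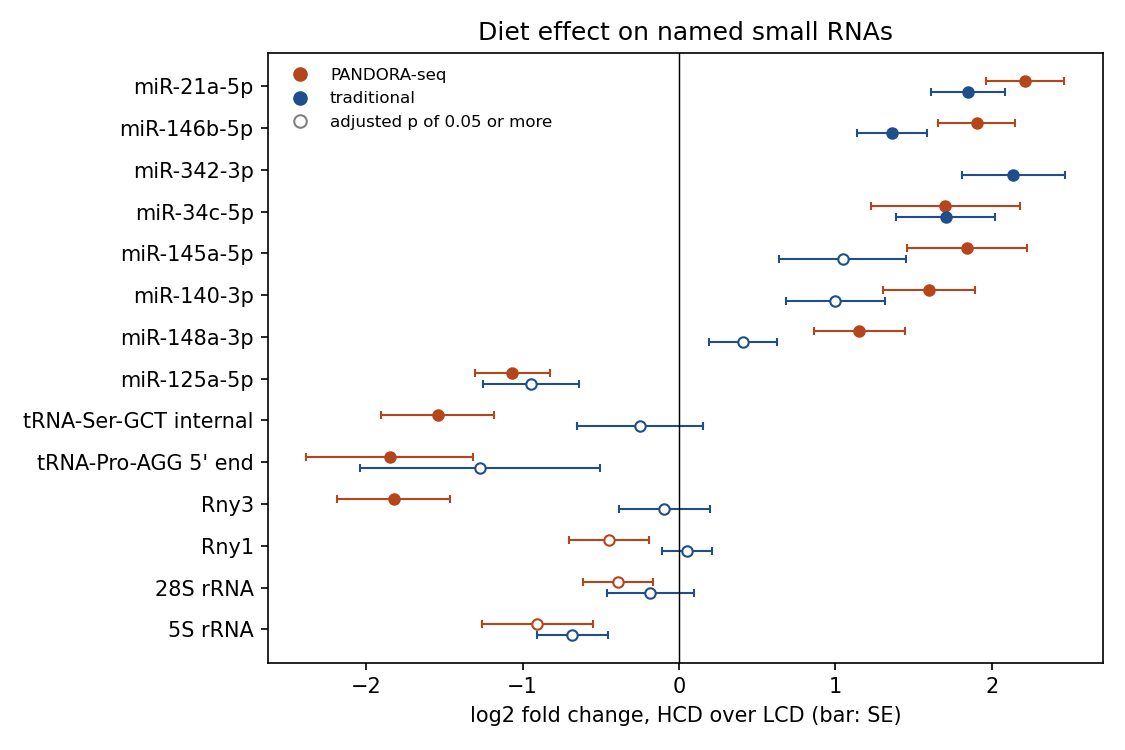
log2 fold change of HCD over LCD (x axis) for 14 small RNAs in PANDORA-seq and traditional libraries, with SE as bars; open points have an adjusted p of 0.05 or more. miR-21a-5p lies at 2.21 in PANDORA-seq and 1.85 in traditional libraries, and Rny3 at −1.82 and −0.09.

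Lists of miRNAs fixed beforehand were tested as groups in the PANDORA-seq fit. Of 6 measured myeloid and inflammation miRNAs, 3 rose and none fell (4 adjusted over the list alone). miR-21a-5p and miR-146b-5p led them, the latter, which restrains NF-kB signalling, with a rise of 1.90 ± 0.25 (adjusted p = 0.000498, edgeR). The group was higher on HCD (camera, adjusted p = 4.14e-05), also with an estimated correlation between members (adjusted p = 0.0426). Of 6 smooth muscle miRNAs 3 rose (5 adjusted over the list alone; camera adjusted p = 0.00121, but adjusted p = 0.4 with an estimated correlation), with miR-145a-5p past the threshold and miR-143-3p at 1.12 ± 0.35 (adjusted p = 0.0516, edgeR). miR-143-3p passed in 10 of its 21 alternatives, with values from 0.94 to 1.34. The 3 fibrosis miRNAs were higher as a group (camera adjusted p = 0.00782, adjusted p = 0.4 with an estimated correlation), with 1 of them, miR-21a-5p, past the threshold and miR-199a-5p at 0.51 ± 0.31. Fragments of tRNA Ala (2 of 7 features fell, 5 adjusted over the list alone) and tRNA Pro (4 of 10 fell, 5 adjusted over the list alone) were lower as groups (camera adjusted p = 0.0283 and 0.00782, adjusted p = 0.565 for both with an estimated correlation). In the miR-30 family 2 of 4 measured members rose, miR-30a-5p by 0.82 ± 0.21 and miR-30d-5p by 0.72 ± 0.22 (adjusted p = 0.0250 and 0.0444, edgeR). The miR-30a-5p call ended without 5 of the 9 libraries (0.79 to 0.95, adjusted p up to 0.0657) and that of miR-30d-5p without 7 (0.61 to 0.84, up to 0.128), and the family had an adjusted p of 0.0518 in camera. Cholesterol and lipid miRNAs had 2 of 9 risen (camera adjusted p = 0.0518), endothelial miRNAs 1 of 9 (adjusted p = 0.638), liver miRNAs 1 of 3 (adjusted p = 0.674) and striated muscle miRNAs 1 of 3 (adjusted p = 0.132). Lymphocyte miRNAs (adjusted p = 0.432) and the let-7 family (adjusted p = 0.638) had none of 4 and 9 members past the threshold. The lists of erythroid, neuronal, epithelial and adipocyte miRNAs and of the miR-17-92 cluster had fewer than 3 measured members and were not tested. Values of members that did not pass were 0.18 ± 0.32 for miR-10a-5p and 0.18 ± 0.31 for miR-10b-5p (endothelial), 0.27 ± 0.24 for miR-29a-3p and 0.36 ± 0.28 for miR-181b-5p (lymphocyte), 0.74 ± 0.37 for miR-1a-3p (1.28 without LCD_PANDORA replicate 4, which passed, as it did with a replicate block at an adjusted p of 0.00932) and 0.38 ± 0.34 for miR-206-3p (0.08 without HCD_PANDORA replicate 3; striated muscle), and 0.01 ± 0.29 for let-7c-5p and 0.56 ± 0.30 for let-7f-5p. The liver miRNA miR-122-5p had −4.02 ± 1.98 (adjusted p = 0.25, edgeR) and 1.83 without LCD_PANDORA replicate 1, and the median of the liver list (0.13) and its mean (−0.91) differ in sign. The group calls numbered 3 without LCD_PANDORA replicate 2 and 8 without HCD_PANDORA replicate 2, against 5. Without LCD_PANDORA replicate 2 all 3 were higher and 0 lower, so the calls of tRNA Ala and tRNA Pro both rest on that library.

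In traditional libraries the same diet contrast called 7 of 945 features, 6 higher and 1 lower on HCD (n = 5 and 4). miR-342-3p, expressed in lymphoid and myeloid cells, rose by 2.14 ± 0.33 (log2 ± SE; adjusted p = 0.0206, edgeR), and miR-21a-5p by 1.85 ± 0.24, from 6880 ± 1250 to 24700 ± 6740 CPM (mean ± SD; adjusted p = 0.00771, edgeR). miR-34c-5p, a target of p53, rose by 1.70 ± 0.32 (adjusted p = 0.0438, edgeR) and miR-146b-5p by 1.36 ± 0.23 (adjusted p = 0.0278, edgeR). Internal pieces shared by tRNA-Leu-CAA and tRNA-Leu-CAG fell by 1.33 ± 0.26 (adjusted p = 0.0440, edgeR). The other 2 calls, miR-34a-5p (2.36 ± 0.43, adjusted p = 0.0438, edgeR) and miR-7091-3p (1.38 ± 0.27, adjusted p = 0.0440), fell below the 10 CPM of the naming rule and were chosen after their values were seen. For each of the 5 named first, all HCD libraries lay beyond all LCD libraries. Other RNAs did not pass, the lowest p-values belonging to reads of mRNA transcripts (−1.0 ± 0.31), the snoRNA gene AF357425 (−0.59 ± 0.19) and 5S rRNA (−0.68 ± 0.23). Rny3 had −0.09 ± 0.29 and Rny1 0.05 ± 0.16. Among rRNA species, 28S rRNA had −0.18 ± 0.28, 18S rRNA −0.49 ± 0.42, 5.8S rRNA 0.09 ± 0.62, mt-12S rRNA −0.20 ± 0.30 and mt-16S rRNA −0.28 ± 0.23. Of 556 features tested in both methods, 3 were called in both with the same sign, and 56 of the 62 PANDORA-seq calls among them had the same sign in traditional libraries, against 352 of all 556 (63.3%). Both contrasts can rest on the same samples, so this is not an independent repeat. Without LCD_traditional replicate 4 each of the 5 calls ended, miR-21a-5p having 1.79 (adjusted p = 0.0511, edgeR). That of miR-21a-5p held without each other library, while miR-342-3p lost its call without 3 of 9 libraries (1.95 to 2.29, adjusted p up to 0.0607), miR-146b-5p without 5 (1.22 to 1.47, up to 0.109), miR-34c-5p without 7 (1.56 to 1.88, up to 0.18) and the tRNA-Leu pieces without 7 (−1.51 to −1.14, up to 0.18). The tRNA-Leu value was −0.70 without reads under 18 nt (adjusted p = 0.367, edgeR). DESeq2 called 74 features and the fit with total reads as library size 1. The count was 0 without LCD_traditional replicate 4 and 23 without HCD_traditional replicate 5, and lay between 1 and 4 without each of the 7 other libraries.

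The miRNA lists were tested in the traditional fit as well. Of 16 myeloid and inflammation miRNAs 3 rose (13 adjusted over the list alone), and the group was higher on HCD (camera adjusted p = 3.36e-12, adjusted p = 0.113 with an estimated correlation). Smooth muscle miRNAs were higher as a group (camera adjusted p = 0.00967, adjusted p = 0.757 with an estimated correlation) with none of 6 past the threshold, miR-143-3p at 0.59 ± 0.27 and miR-145a-5p at 1.05 ± 0.41. Epithelial miRNAs were higher as a group (camera adjusted p = 0.00339, adjusted p = 0.757 with an estimated correlation), with none of 7 past the threshold over all features, miR-200b-3p at 2.03 ± 0.58 (1.30 without HCD_traditional replicate 1) and miR-203-3p at −0.72 ± 0.22. Fibrosis miRNAs were higher as well (1 of 7 past the threshold, miR-21a-5p; camera adjusted p = 0.00526, adjusted p = 0.757 with an estimated correlation). Endothelial miRNAs had 1 of 12 risen (camera adjusted p = 0.816), with miR-10a-5p at −0.31 ± 0.20 and miR-126a-3p at −0.40 ± 0.18, and lymphocyte miRNAs 1 of 7 (adjusted p = 0.107), with miR-29a-3p at 0.04 ± 0.15 and miR-181a-5p at −0.09 ± 0.16. No member passed in the lists of the miR-17-92 cluster (camera adjusted p = 0.71; miR-25-3p −0.22 ± 0.18, miR-92a-3p −0.58 ± 0.22), cholesterol and lipid (0.816; miR-148a-3p 0.41 ± 0.22, miR-26a-5p −0.10 ± 0.16) or erythroid miRNAs (0.815; miR-16-5p 0.25 ± 0.18, miR-451a-5p −0.48 ± 0.52). The same held for striated muscle (0.816; miR-1a-3p 0.39 ± 0.32, miR-206-3p −0.18 ± 0.32), neuronal (0.723; miR-9-5p −0.27 ± 0.41, miR-128-3p −0.52 ± 0.42) and adipocyte miRNAs (0.895; miR-378a-3p −0.76 ± 0.20, miR-365-3p −0.03 ± 0.21). It also held for the let-7 family (0.816; let-7f-5p 0.21 ± 0.20, let-7i-5p 0.38 ± 0.16), the miR-30 family (0.723; miR-30a-5p 0.46 ± 0.25, miR-30d-5p 0.04 ± 0.14) and liver miRNAs (0.723). The liver miRNA miR-122-5p had −4.61 ± 1.57 (adjusted p = 0.147, edgeR) and 1.01 without LCD_traditional replicate 1.

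Single sequences can move apart from the RNA they come from, so each distinct miRNA, tRNA, rRNA and Y RNA sequence was tested too. With PANDORA-seq the 36-nt fragment of 28S rRNA with the largest fall went from 979 ± 567 to 62.9 ± 14 CPM on HCD (mean ± SD; −3.96 ± 0.58, adjusted p = 0.00525, edgeR), and a 33-nt fragment with the same 5' end had −3.86 ± 0.53 (adjusted p = 0.00500). A 17-nt and a 16-nt fragment of 18S rRNA rose by 3.55 ± 0.72 and 3.07 ± 0.74 (adjusted p = 0.0190 and 0.0368, edgeR). Fragments of 37 nt from the 3' ends of tRNA-Arg-CCG and tRNA-Arg-ACG rose by 2.06 ± 0.49 and 1.80 ± 0.48 (adjusted p = 0.0360 and 0.0494, edgeR), and internal tRNA-Ser-GCT fragments of 45 and 44 nt fell by 2.73 ± 0.55 and 2.53 ± 0.59 (adjusted p = 0.0197 and 0.0343, edgeR). The 18S rRNA and tRNA-Ser-GCT fragments moved as read lengths did as a whole on HCD, with reads of 45 nt going from 5.99% ± 1.76 to 2.86% ± 1.27 of PANDORA-seq reads and reads of 17 nt from 0.491% ± 0.0557 to 0.883% ± 0.264 (SD, n = 4 and 5). Of 113 Y RNA sequences 42 fell and none rose. In total 785 of 20195 sequences passed, 252 higher and 533 lower. Among them were 596 of 16144 tested rRNA, 78 of 1938 tRNA and 31 of 1011 miRNA sequences, so most calls were rRNA because most tested sequences were. As groups, 5S rRNA sequences were lower (camera adjusted p = 1.07e-06, adjusted p = 0.662 with an estimated correlation) and mt-12S rRNA sequences higher (4.29e-05, adjusted p = 0.991 with an estimated correlation). In traditional libraries edgeR called 0 of 19586 sequences, with 1327 at an unadjusted p under 0.05, and DESeq2 called 141. Among tRNA and rRNA sequences, those of lowest p there included 3' ends of mt-tRNA-g (45 nt, −3.38 ± 0.56) and mt-tRNA-h (45 nt, −3.52 ± 0.60) and a 45-nt piece of 5S rRNA (−2.92 ± 0.42), and none of these passed. As groups, sequences of 28S, 18S and 5S rRNA were lower and those of mt-12S and mt-16S rRNA higher in camera (adjusted p from 3.91e-05 to 0.0185), all of which ended with an estimated correlation (adjusted p from 0.567 to 0.675). Camera compares a group with the other sequences: the medians of mt-12S and mt-16S rRNA were 0.22 and 0.10, that of 28S rRNA −0.24. As features in the traditional fit, both mitochondrial rRNAs had negative values, so the 2 levels differ in sign. Both 28S rRNA fragments held without each library (highest adjusted p = 0.0306, edgeR), and the tRNA and 18S rRNA fragments lost their calls without 3 to 8 of the 9 libraries, 8 for tRNA-Arg-ACG (adjusted p up to 0.142). The 44-nt tRNA-Ser-GCT fragment had −1.68 without LCD_PANDORA replicate 2 (adjusted p = 0.134, edgeR). The PANDORA-seq count was 91 without LCD_PANDORA replicate 2 and 2775 without HCD_PANDORA replicate 5, and lay between 150 and 1509 without each of the others, while DESeq2 called 3215.

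Between the methods, nearly every small RNA changed its share of the reads (all 18 libraries, diet as covariate, PANDORA-seq over traditional). The 5 miRNAs with the largest fall were miR-142a-5p at −10.12 ± 0.37 (log2 ± SE), miR-136-3p at −10.03 ± 0.36, miR-30a-5p at −9.85 ± 0.32, miR-340-5p at −9.81 ± 0.29 and miR-101a-3p at −9.81 ± 0.32 (highest adjusted p = 5.36e-19, edgeR). The tRNA fragments that rose most were 3' ends of tRNA-Leu-CAA by 7.65 ± 0.49, tRNA-Arg-CCG by 7.27 ± 0.43, tRNA-Ser-GCT by 6.29 ± 0.32 and tRNA-Gly-GCC by 6.18 ± 0.33, with internal tRNA-Ser-GCT pieces at 6.11 ± 0.36. CCA ends of tRNA-Tyr-GTA fell by 8.56 ± 0.36, internal pieces of mt-tRNA-s2 by 6.63 ± 0.48 and of tRNA-Lys-TTT by 5.42 ± 0.28, the 5' end of mt-tRNA-s1 by 4.53 ± 0.27 and internal pieces shared by tRNA-Gln-CTG and tRNA-Gln-TTG by 4.36 ± 0.45. All 4 rRNA species rose, 28S rRNA by 3.78 ± 0.20, 18S rRNA by 3.78 ± 0.31, 5S rRNA by 1.66 ± 0.24 and 5.8S rRNA by 1.06 ± 0.32, and mt-12S rRNA rose by 1.70 ± 0.28, with mt-16S rRNA at 0.40 ± 0.24. The mt-16S rRNA value depends on the scaling, since it passed at 1.65 with TMM and also with DESeq2, and it passed at 0.51 without LCD_traditional replicate 3. RNase P RNA rose by 6.98 ± 0.30, Snora57 by 6.16 ± 0.30 and Snord35a by 5.67 ± 0.31, and Snord85 fell by 3.37 ± 0.23, Snord87 by 2.80 ± 0.20 and Scarna17 by 1.91 ± 0.18. Rny3 rose by 1.34 ± 0.26, and Rny1 had −0.19 ± 0.17 (1.09 with TMM scaling, adjusted p = 1.64e-06, edgeR). Features of predicted miRNA genes that rose were the Gm22002-5p groups r (5.25 ± 0.55) and k (5.03 ± 0.32) and 3 features of Gm47276 and related genes (2.88 ± 0.40 to 3.92 ± 0.41), of whose reads 100% also match rRNA. In total 991 of 1083 features passed, 312 higher and 679 lower with PANDORA-seq, among them 536 of 711 miRNA features lower. The median of all features was −2.92, and −1.85 with TMM scaling.

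Whether the diet effect differed between the methods was tested with an interaction term over all 18 libraries. The lowest p-values belonged to the 3' ends of mt-tRNA-i (2.98 ± 0.70, log2 ± SE) and mt-tRNA-v (2.60 ± 0.63), to Gm22133-3p (2.62 ± 0.65), the snoRNA Snora34 (2.74 ± 0.71) and miR-6516-5p (2.77 ± 0.74), each with a larger HCD over LCD ratio in PANDORA-seq and an adjusted p of 0.167 or 0.182 (edgeR). The mt-tRNA-v 3' end went from 297 ± 133 to 124 ± 60.6 CPM in traditional and from 21.9 ± 4.00 to 55.0 ± 22.4 CPM in PANDORA-seq libraries (mean ± SD, n = 4 LCD and 5 HCD). The median of all features was 0.25, and 0.56 with total reads as library size. No feature passed: edgeR called 0 of 1089, with 106 at an unadjusted p under 0.05, and DESeq2 called 8. A block on the replicate number, which assumes that numbers pair the samples between the methods within a diet, called 14, 12 of them higher.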

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

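Of the tests given here, those of the long reads by class and of the length within 28S rRNA were set before their results were seen, and the others were chosen or worded after. The decision rules for insect reads by diet and for both tests of 5.8S rRNA were tightened once their values were known.

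In 8 of 138 comparisons within a group, 1 library lay far from the others (5.8%, where chance gives about 1 in 20). LCD_PANDORA replicate 2 had 128 CPM of the tRNA-Pro-AGG 5' end, against 16.8 to 34.1 in the other LCD PANDORA-seq libraries. HCD_traditional replicate 2 had 194 CPM of Rny3, against 77.6 to 105.3 in its group. HCD_traditional replicate 5 had 52840 CPM of 5.8S rRNA, against 10590 to 15670, and 38.6% unannotated reads, against 22.4% to 26.5%. An insect rRNA stretch found among unmatched reads, described below, took 15.3% of its reads. HCD_PANDORA replicate 5 had mean lengths of 24.5 nt in miRNA (others 21.8 to 22.1 nt) and 36.1 nt in rRNA (others 35 to 35.3 nt). LCD_traditional replicate 1 had 0.714% snoRNA and snRNA reads, against 0.594% to 0.609%. HCD_PANDORA replicate 5 had 0.714% of reads with an insect rRNA stretch, against 0.0133% to 0.107%.

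Unmatched reads carried a stretch of a small rRNA known from flies, and it was the most abundant stretch among them. It took 4.94% of reads on average in LCD traditional, 6.76% in HCD traditional, 0.0884% in LCD PANDORA-seq and 0.201% in HCD PANDORA-seq libraries, where a count of 0 would allow 3 reads per library. Unannotated reads took 27.1% of LCD traditional and 16.9% of LCD PANDORA-seq reads, so the stretch is part of that difference between the methods. Any insect reads that match the reference, whose rRNA and tRNA were rebuilt from these same reads, were not set apart. They would count in the mouse shares and fold changes, and how many there are was not tested. Of 9 insect miRNAs searched, bantam had 11086 reads and miR-275 had 18222, and at least 3 reads of the set were found in 18 of 18 libraries, while miR-277 had 0. Over the 9 traditional libraries their share followed that of the stretch (Spearman's rho 0.833, exact permutation p = 0.00827; Pearson's r 0.929, exact permutation p = 0.000739, and 0.669 without the 2 libraries farthest from the median). That is consistent with RNA of an insect in the libraries. Same-numbered libraries of both methods varied together in it around the means of their groups (r 0.945 over 9 pairs of centred log10 shares, exact permutation p = 0.000347), so it may have entered before samples were divided between the methods, and parallel handling of same-numbered libraries stays open. By diet, the traditional libraries had 6.76% ± 5.24 on HCD and 4.94% ± 4.05 on LCD (exact permutation p = 0.611), which leaves a diet difference open. HCD libraries numbered 5 had the highest share in each method, 15.3% and 0.714%. Without that library the diet contrast called 23 instead of 7 features in traditional and 103 instead of 77 in PANDORA-seq libraries.

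HCD PANDORA-seq reads were shorter by 1.55 nt in rRNA, with −0.586 nt in tRNA. Within 28S rRNA the mean length was −1.49 nt on HCD relative to LCD (35.3 against 36.8 nt, exact permutation p = 0.0159), so a shift between 28S, 18S, 5.8S and 5S rRNA is not the whole cause, although a different choice of pieces within 28S rRNA stays open as a biological explanation. A narrower size range taken from the gel, or loss of long inserts, may lower long reads in every class. Reads of 40 nt and over, as a share of those of 30 nt and over, were lower on HCD in 4 of 5 classes at an exact permutation p under 0.05. These were tRNA (2.32% against 3.67%, p = 0.00794), unannotated reads (30.7% against 38.4%, p = 0.0159), other annotated reads (33.9% against 43.8%, p = 0.0238) and rRNA (32.9% against 42.0%, p = 0.0476), while snoRNA and snRNA had 35.8% against 41.5% (exact permutation p = 0.0556). The labels give no gel lane or batch, so this cannot be told apart from diet. RNA breakage in the HCD samples could shorten rRNA in both methods, and in traditional libraries the exact permutation p of rRNA length was 0.421, which decides nothing.

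5.8S rRNA took 3.46% of reads in HCD_traditional replicate 5 and 2.98% in LCD_traditional replicate 4, against 0.436% to 1.73% in the other traditional libraries. Reads of the insect could match conserved parts of 5.8S rRNA. Over the 9 libraries its share had a rho of −0.15 with the insect stretch (exact permutation p = 0.708; r 0.376, exact permutation p = 0.314, and −0.14 without the 2 libraries farthest from the median). Without HCD_traditional replicate 5, which was highest in both shares, rho was −0.643, so the other libraries show no rise with the insect stretch, while that library itself is not decided. HCD_traditional replicate 5 also had the fewest reads, 16912688, and the share had a rho of −0.717 with total reads (exact permutation p = 0.0369; r −0.666, exact permutation p = 0.048). Without HCD_traditional replicate 5 rho was −0.595, and without the 2 libraries farthest from the median depth r was −0.119, so depth stays open. No biological explanation was tested.

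Other splits of the samples, 100 per comparison with the real one included, gave these results. For the PANDORA-seq diet effect on features, only the real split gave as many as 77 calls, and the highest other gave 57. In the method effect likewise only 1 split, the real one, gave 991, with 0 as the highest other. Chance is therefore an unlikely account of these counts. For the traditional diet effect 2 splits lay at or above the real 7, with 23 as the highest other. For PANDORA-seq sequences 3 splits lay at or above 785. Counts of that size were rare among the splits, but chance cannot be excluded there. Among the other splits, the highest called 2242 PANDORA-seq sequences and 642 traditional ones, which may point to a structure of the samples apart from diet, and none was tested. Chance cannot be excluded for the miRNA and fragment lists, where 24 splits gave as many as the real 5 in PANDORA-seq (highest other 14) and 16 as many as the real 4 in traditional libraries (highest other 6). For traditional sequences and for the interaction the real count was 0, which each of the 100 splits reaches by construction, so these splits decide nothing (highest other 642 and 2).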

How the results depend on the processing

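Alternatives that allow 1 mismatch, put rRNA and tRNA before miRNA, keep at most 35 nt, or apply to the lists and the length profile were added after the data were seen. Apart from leaving out libraries, 1223 of 1350 single values and 45 of 71 counts of calls kept their direction and their side of the threshold (counts within 1.5 times). The rise of miR-21a-5p, miR-145a-5p and miR-140-3p with PANDORA-seq held in each of their 21 alternatives, the first between 2.06 and 2.47. Where no reason is given, the cause was not tested.

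DESeq2 called 3215 instead of 785 PANDORA-seq sequences, 74 instead of 7 traditional features, 141 instead of 0 traditional sequences and 8 instead of 0 interactions. It gave let-7c-5p 0.00 in PANDORA-seq, and Rny1 1.00 in the method effect, where TMM gave 1.09 (−0.19 with total reads). With total reads as library size the diet calls were 49 instead of 77 in PANDORA-seq (42 shared, 37 higher and 12 lower) and 1 in traditional libraries. The median of all features moved from 0.04 to 0.29 and from −0.03 to −0.19, so the balance of directions follows the scaling. In traditional libraries Rny1 then had −0.12, 5.8S rRNA −0.11, miR-29a-3p −0.12 and miR-30d-5p −0.13. TMM from miRNA features called 76 in PANDORA-seq (median −0.10), with let-7c-5p at −0.16 and mt-16S rRNA at −0.01, and 3 in traditional libraries, with miR-29a-3p at 0.00.

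A mean of at least 10 CPM, with fewer tested, called 30 PANDORA-seq features (25 shared), 68 PANDORA-seq sequences (67 shared) and 8 traditional sequences. A mean count of at least 1 called 1573 PANDORA-seq and 10 traditional sequences. With no filter beyond a count above 0, 80 traditional features and 1879 in the method effect were called. A fit of all 18 libraries called 44 features in PANDORA-seq and 16 in traditional libraries.

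A replicate block, which assumes that numbers pair the samples between diets, called 158 PANDORA-seq features, 2249 PANDORA-seq sequences and 27 traditional features. For the interaction the block pairs numbers between the methods within a diet instead, and it called 14. Under the block between diets 5.8S rRNA had −0.30 and miR-365-3p 0.08 in traditional libraries. Other annotated reads had 0.0304 points in PANDORA-seq and unannotated reads −2.83 points in traditional libraries. Blocks on the number called 0 class shares by method on LCD, 0 on HCD and 0 in the length profile, since 4 or 5 pairs cannot pass.

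Reads of at most 35 nt gave 46 PANDORA-seq features, with let-7c-5p at −0.16 and 5.8S rRNA at 0.29. let-7c-5p had 0.00 from sequences with 1 name and −0.02 with rRNA and tRNA before miRNA. With 1 mismatch miR-1a-3p had −0.11 and unannotated PANDORA-seq reads 0.367 points by diet. An estimated correlation left 1 list in PANDORA-seq and 0 in traditional libraries.

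Leaving out 1 library gave 17 (without LCD_PANDORA replicate 1) to 103 PANDORA-seq features (without HCD_PANDORA replicate 5), 91 (without LCD_PANDORA replicate 2) to 2775 sequences (without HCD_PANDORA replicate 5) and 3 to 8 lists. It gave 0 (without LCD_traditional replicate 4) to 23 traditional features (without HCD_traditional replicate 5) and 0 to 1 interactions. Of single values 1960 of 2142 kept direction and side. Those that changed sign follow. In PANDORA-seq miR-122-5p ran from −5.04 to 1.83, 18S rRNA from −0.08 to 0.49, miR-10a-5p from −0.01 to 0.44, miR-10b-5p from −0.01 to 0.41, let-7c-5p from −0.21 to 0.19 and mt-16S rRNA from −0.11 to 0.28. In traditional libraries miR-122-5p ran from −5.05 to 1.01, 5.8S rRNA from −0.63 to 0.75, miR-365-3p from −0.11 to 0.08, mt-12S rRNA from −0.39 to 0.14, miR-206-3p from −0.48 to 0.06, Rny3 from −0.42 to 0.02, miR-9-5p from −0.53 to 0.10, Rny1 from −0.01 to 0.11, miR-30d-5p from −0.03 to 0.10 and miR-29a-3p from −0.03 to 0.08. Class shares by diet ran in PANDORA-seq from −0.00152 to 0.206 points for snoRNA and snRNA, −0.33 to 1.84 for rRNA, −0.532 to 0.297 for other annotated and −0.763 to 0.108 for unannotated reads, and in traditional libraries from −2.83 to 2.09 for unannotated reads.

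Shares of genome-matched reads were not run, for lack of a genome sequence. At this depth, simulated changes of 2-fold were recovered for 60% of PANDORA-seq features but 1.5% of single sequences, so small changes of sequences would be missed.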

Other observations

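The values in this part were chosen after they were seen, and no explanation was tested. Beyond the features named by rule, PANDORA-seq calls on HCD included the rises of miR-23b-3p (2.38 ± 0.45, log2 ± SE, n = 4 LCD and 5 HCD; adjusted p = 0.0104, edgeR), miR-23a-3p (2.07 ± 0.48) and miR-27b-3p (0.94 ± 0.26), which is encoded beside miR-23b. Both arms of the miR-145a hairpin rose, miR-145a-3p by 1.12 ± 0.27, and so did both arms of miR-140, miR-140-5p by 0.98 ± 0.28. miR-146a-5p rose by 0.79 ± 0.24 and miR-221-3p by 1.08 ± 0.29. Of these, miR-23b-3p, miR-23a-3p, miR-145a-3p and miR-221-3p fell below the mean of 10 CPM that the naming rule asks for. No values without single libraries are given for these miRNAs.

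Of 143 snoRNAs tested with PANDORA-seq, 7 were called and all were lower on HCD, no larger a share than that of lower calls among all features (42 of 688). The class of snoRNA and snRNA took 1.22% ± 0.136 of reads on HCD (SD, n = 5) and 1.12% ± 0.322 on LCD (SD, n = 4), so no fall of the class was seen. The U3 genes Rnu3b1 to Rnu3b4, counted together, went from 409 ± 126.0 to 187 ± 45.7 CPM (mean ± SD; −1.13 ± 0.29), Snord111 had −0.85 ± 0.22, Scarna10 −0.92 ± 0.25 and Snora64 −0.96 ± 0.25. RNase P RNA went from 429.8 ± 188 to 205 ± 57.1 CPM (−1.07 ± 0.33).

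The 3 features called in both methods were miR-21a-5p, miR-146b-5p and miR-34c-5p, the last with a rise of 1.70 ± 0.32 in traditional and 1.70 ± 0.48 in PANDORA-seq libraries. With PANDORA-seq, miR-146b-5p (mean 6.13 CPM) and miR-34c-5p lay below 10 CPM. In traditional libraries the miR-34c-5p call ended without 7 of 9 libraries, that of miR-146b-5p without 5 and that of miR-21a-5p without 1.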
